A study of Mus musculus with 4 samples.

How the data were processed

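Total RNA was taken from whole testes of male B6D2F1 mice at 24 days and made into libraries with a TruSeq RNA kit, per the labels' protocols. There were 4 libraries, 2 wild type and 2 homozygous for the Adad2 knockout. The submitters' processing notes name bcl2fastq 2.17.1.14, Bowtie2 without a version, and the mm9 genome. The counting tool, the annotation release, the use of strand and any filter are not given in the sources used here. TruSeq kits exist with and without strand marking, so reads of overlapping and antisense genes may not have been told apart.

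The authors deposited a table of log2 RPKM values (reads scaled to gene length and library depth) with 26127 entries, of which 59 (0.23%) name no gene and were left out of the tests. The column names call the groups control and null with a number, and were matched to the labels by group and number. The authors' mean columns equalled the means of the numbered columns and were not used. No column of sample values was left unmapped. The table gives no read counts. In genes with a single annotated exon, low values fell on whole multiples of what 1 read is worth: 96.9% to 97.5% of values up to 10 reads were whole within 2%. Genes without reads carried 0.9 of a read in place of 0, so logarithms were finite throughout. The depth follows from these steps, about 30200000, 36900000, 33000000 and 29400000 reads, and is an estimate. All 13 mitochondrial genes differed between libraries only by this step, so they were listed at the floor and none was tested. Estimated reads per gene used exon lengths of Gencode M21, matched by gene identifier for 23618 entries; that release is on another genome build, so only names, types and lengths were taken from it. Coordinates are those of the table, in mm9.

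Genes entered the tests when their mean over the 4 libraries was at least 0 on the log2 RPKM scale, which is 1 RPKM. Differences between knockout and wild type were tested with limma 3.58.1 in R 4.3.3, using empirical Bayes with an intensity trend and robust estimation (statmod 1.5.0), unpaired and two-sided, with Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. No pseudocount was added, since the floor was already in the values. Fold changes are differences of mean log2 values, and folds of genes close to the floor are understated. Intervals are 95% confidence intervals from the same model. With 2 libraries against 2, no exact permutation test can give a two-sided p below 0.333, so calls rest on the spread that limma pools across genes.

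The tests of the report, the rule for naming genes and 18 gene lists were fixed before the data were examined, while several tests of the closing section were chosen afterwards. Lists were tested with camera at a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment was made over the lists, and for chromosomes X and Y over those sets. This preset takes the genes of a list as nearly independent, so its very small p-values do not measure the spread between libraries. The correlation estimated from the data was 0.649 for the acrosome list and 0.833 for the elongating spermatid list. The lists cover the piRNA pathway, deaminase family, spermatogonia, early meiotic prophase, pachytene spermatocytes, acrosome, elongating spermatids, spermiogenesis regulators, motile cilium, germ cell glycolysis, Sertoli, Leydig, peritubular and endothelial, immune and red blood cells, interferon, p53 and stress, and sex chromosome spermatid genes. Camera was repeated with the correlation estimated from the residuals, and no list was past the threshold then. With 4 libraries this repeat has few degrees of freedom. The elongating spermatid list, with 39 of 39 tested members below 0, had an unadjusted camera p of 0.105 in it. Missing the threshold there is therefore weak evidence against a shift. Adad2 and 12 core genes were fixed by name, and the rule took the others from the results: the 8 largest increases and 8 largest decreases past the threshold with groups that did not overlap and with symbols other than clone names, and in each list 2 to 4 tested members with the smallest p. Where a symbol had several entries, the entry with the highest mean stood for it. A gene that the rule names is not reported here.

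Alternatives were no filter, a filter at a mean of 2 on the log2 scale, log2(RPKM + 1), quantile normalization, equal library medians, limma without trend and robust estimation, the replicate number as a block, other thresholds, and leaving out each library in turn. Leaving out a library leaves its group with a lone library, which is then assumed to vary like the other group. The code was tested on simulated data for this comparison, with 13414 genes and 200 of them changed. It recovered 11.9% of changes of 0.5, 80.6% of changes of 1 and 98.5% of changes of 2 on the log2 scale, with 7 false calls. A shifted list of 30 genes was called, and 1 of 100 random lists had p under 0.05. The simulated genes were drawn independently, so this rate does not apply to lists whose genes move together. Figures were drawn with matplotlib 3.10.9.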

Results

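Messenger RNA levels were measured by RNA sequencing in whole testes of 24-day-old male B6D2F1 mice, a hybrid of inbred strains. At this age the first wave of spermatogenesis has passed meiosis and spermatids are forming. There were 2 libraries from wild type and 2 from homozygous Adad2-knockout testes. Adad2 encodes a germ cell protein with a double-stranded RNA binding domain and a domain related to adenosine deaminases. The series' title places the question in piRNA production and in spermiogenesis, the shaping of spermatids into sperm. The table gives RPKM per gene on the log2 scale and no read totals. The value of a single read put the depth at about 30200000 and 36900000 reads for wild type replicates 1 and 2, and 33000000 and 29400000 reads for knockout replicates 1 and 2. A single read in a gene of 1 kb was worth 0.0271 to 0.034 RPKM. Across 13414 genes the wild type libraries correlated at r = 0.989 and the knockout libraries at r = 0.985, against 0.909 to 0.95 between the groups. These correlations are across genes, which are not independent replicates. The labels do not say whether replicates are separate animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical. The p-values of gene lists at the preset correlation set genes against genes and do not measure that spread.

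Adad2 itself fell in the knockout. Its log2 RPKM was 4.66 and 4.47 in the wild type libraries and 3.73 and 3.30 in the knockout libraries. The group values were 4.56 ± 0.13 and 3.51 ± 0.30 (mean ± SD, n = 2 each), a 2.07-fold lower level in the knockout. The change was -1.05 (SE 0.16, 95% confidence interval -1.42 to -0.68) with a limma adjusted p = 0.00604. Adad2 lies on the plus strand of chromosome 8 from 122136647 to 122140826 in mm9 (ENSMUSG00000024266). The values are per gene, so they do not show which part of the gene was deleted, and transcript from Adad2 was still measured in both knockout libraries. The change stayed negative but missed the threshold without wild type replicate 1 (adjusted p = 0.143) or without wild type replicate 2 (adjusted p = 0.0838), which left a lone wild type library.

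Prm1, Prm2 and Tnp1, genes of haploid germ cells, fell in the knockout by more than any called gene rose. Prm1 and Prm2, the protamines that package sperm DNA, were 39.2-fold and 40.8-fold lower. Tnp1, the transition protein that precedes them, was 32.7-fold lower (log2 change -5.03, SE 0.44, n = 2 per group, limma adjusted p = 0.00999). Stambp, which encodes a deubiquitinase, rose 2.73-fold, from 4.59 ± 0.03 to 6.04 ± 0.16 log2 RPKM (adjusted p = 0.000278). Of 13414 genes tested, 959 were lower and 163 higher in the knockout at a Benjamini-Hochberg adjusted p under 0.05. Among these, 660 of the lower and 19 of the higher genes changed by at least 1 on the log2 scale, and 72 fell by at least 3. The median change was -1.38 among the lower genes and 0.58 among the higher genes, beside a median of 0.14 over all genes tested. The counts rest on few libraries. Without wild type replicate 1 limma called 0 genes in either direction, with 2357 genes at an unadjusted p under 0.05, and without wild type replicate 2 it called 288 lower and 22 higher. Without knockout replicate 1 it called 1308 lower and 405 higher, and without knockout replicate 2 it called 1056 lower and 494 higher. A stricter filter at a mean of 4 RPKM gave 637 lower and 220 higher genes, which raised the share of higher calls from 14.5% to 25.7%.

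**Figure D1:**
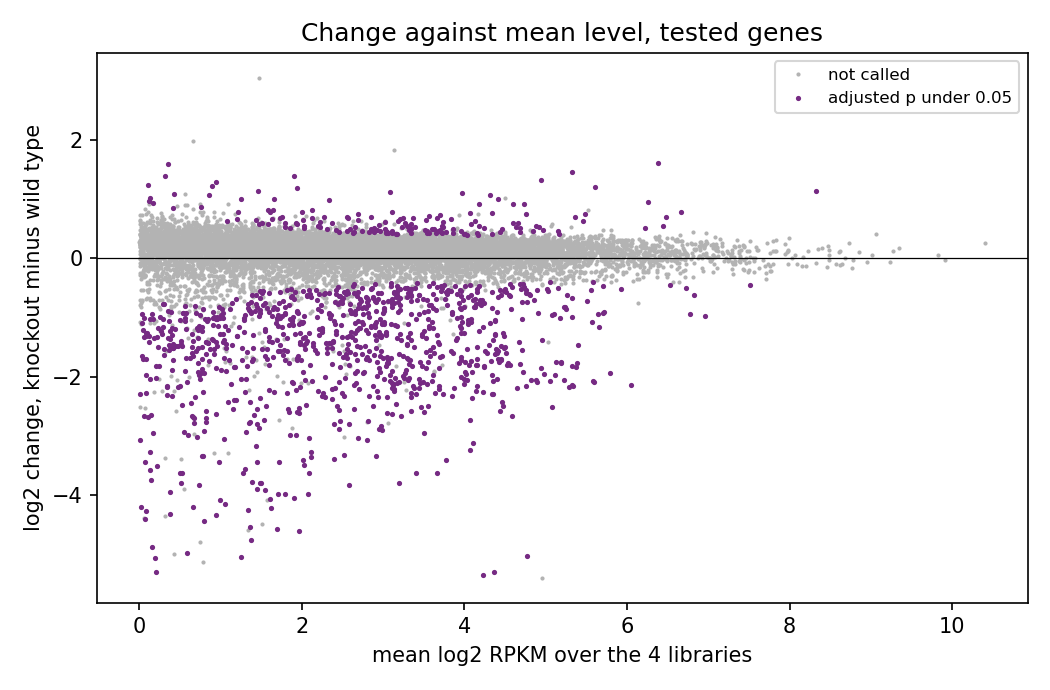
Log2 change (knockout minus wild type) of each of the 13414 tested genes against its mean log2 RPKM over the 4 libraries, with purple points for adjusted p under 0.05 and grey points for the rest. The 959 lower genes reach below -5, while the largest called increase is 1.61.

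Genes of the acrosome and round spermatid, the first haploid stage, fell as a group. Of 34 tested members, 23 fell and 0 rose, with a median log2 change of -1.80 (limma camera adjusted p = 1.53e-25; adjusted p = 0.58 with an estimated correlation). Adjusted over the list alone, 25 fell. Acrv1, an acrosomal matrix protein, fell from 5.68 ± 0.18 to 3.25 ± 0.60 log2 RPKM, 5.41-fold (SD, n = 2, limma adjusted p = 0.0161). Tssk6, a testis-specific kinase, was 10.8-fold lower. Acsbg2, an acyl-CoA synthetase, was 4.41-fold lower. Tssk2 was 5.96-fold lower, although its reads may be shared with the closely related Tssk1. Prss55, a testis serine protease, was 20.2-fold lower. Acrv1 missed the threshold without wild type replicate 2 (adjusted p = 0.0558).

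Genes of elongating spermatids and chromatin condensation fell furthest. Of 39 tested members, 30 fell, 0 rose and 39 had a change below 0, with a median of -2.11 (limma camera adjusted p = 6.97e-42; adjusted p = 0.58 with an estimated correlation). Adjusted over the list alone, 34 fell. Prm1 went from 7.01 ± 0.04 to 1.72 ± 0.85 log2 RPKM (change -5.29, SE 0.45, adjusted p = 0.00916). Spata3, a spermatogenesis-associated gene, was 14.8-fold lower. Ropn1, a fibrous sheath protein of the sperm tail, was 4.18-fold lower. Tekt5, a tektin of the flagellum, was 4.23-fold lower, and Actl7a, an actin-like protein of the sperm head, was 3.78-fold lower. The knockout libraries differed in these genes, with Prm1 at 2.32 in replicate 1 and 1.12 in replicate 2. Prm2 missed the threshold with library medians set equal (adjusted p = 0.063) and with the stricter filter (adjusted p = 0.0808).

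Leaving out genes with clone or predicted names, the 8 largest decreases also held Spem1, of the elongating spermatid list, and genes outside the lists. Fam71b was 39.2-fold lower, Trp53tg5 29.4-fold lower and Cct8l1 21.7-fold lower. Spem1, a spermatid maturation gene, was 27.1-fold lower (log2 change -4.76, SE 0.56, limma adjusted p = 0.019). Their lowest libraries held an estimated 7 reads for Fam71b, 6 for Trp53tg5, 16.1 for Cct8l1 and 9 for Spem1, so the size of these folds is less certain than their direction. Fam71b (adjusted p = 0.0681) and Spem1 (adjusted p = 0.0554) missed the threshold without wild type replicate 2.

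**Figure D2:**
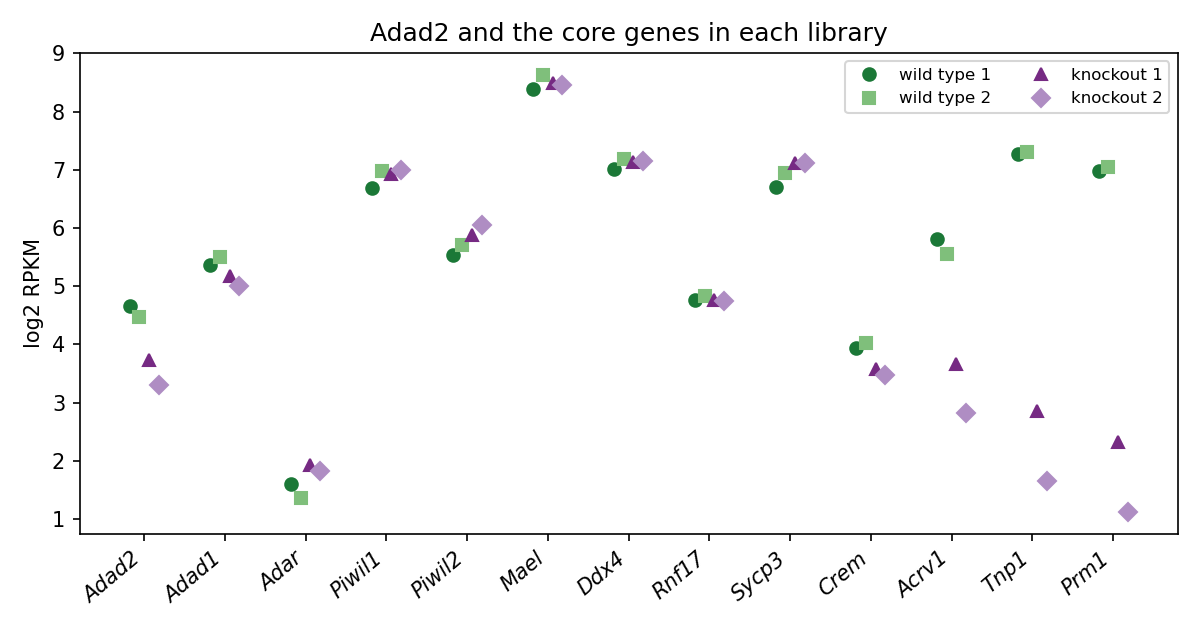
Log2 RPKM of Adad2 and the 12 core genes in each library, with circles and squares for wild type replicates 1 and 2 and triangles and diamonds for knockout replicates 1 and 2. Acrv1, Tnp1 and Prm1 are lower in both knockout libraries, with Prm1 at 6.98 and 7.04 in wild type and 2.32 and 1.12 in the knockout.

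Other groups tied to spermatids moved the same way in part of their members. Of 13 tested genes that spermatids express from, or in families shared with, the sex chromosomes, 7 fell and 0 rose, with a median of -0.84 (limma camera adjusted p = 1.95e-09; adjusted p = 0.58 with an estimated correlation). Adjusted over the list alone, 10 fell. Akap4, the main fibrous sheath protein, was 6.35-fold lower, Tsga8 2.24-fold lower and Actrt1 2.76-fold lower. Cypt4, placed on chromosome 9 in the table, was 5.71-fold lower, although its family members may share reads. Of 24 germ cell glycolysis and mitochondrial genes, 9 fell and 0 rose, with a median of -0.17 (camera adjusted p = 5.81e-06; adjusted p = 0.58 with an estimated correlation), and 10 fell when adjusted over the list alone. Gapdhs, the sperm form of glyceraldehyde phosphate dehydrogenase, was 4.46-fold lower. Slc16a7, a monocarboxylate transporter, was 2.96-fold lower and the hexokinase Hk1 2.09-fold lower. Aldoart2, an aldolase retrogene with close relatives, was 2.60-fold lower. Actrt1 missed the threshold without wild type replicate 2 (adjusted p = 0.0532).

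Regulators of spermiogenesis split. Of 27 tested members, 6 fell, 0 rose and 21 were not called, with a median of -0.11 (limma camera adjusted p = 0.000339; adjusted p = 0.58 with an estimated correlation). Adjusted over the list alone, 8 fell. Crem, the transcription factor that switches on many spermatid genes, was 1.37-fold lower, from 3.98 ± 0.06 to 3.52 ± 0.07 log2 RPKM (SD, n = 2, limma adjusted p = 0.0313). The kinesin Kif17 was 2.82-fold lower, the chromatin remodeller Chd5 3.20-fold lower, and the transcription factors Sox5 and Sox30 3.42-fold and 1.61-fold lower. Of 37 motile cilium and axoneme genes, 4 fell and 33 were not called, with a median of -0.04 (camera adjusted p = 0.0249; adjusted p = 0.807 with an estimated correlation), and 4 fell when adjusted over the list alone. These were the tektins Tekt2 (1.93-fold lower) and Tekt4 (1.91-fold lower), Armc4 (1.68-fold lower) and Foxj1 (1.44-fold lower), the last a transcription factor for motile cilia. Crem missed the threshold without knockout replicate 2 (adjusted p = 0.0845) and without a filter (adjusted p = 0.0823). Without wild type replicate 2 Crem (adjusted p = 0.18), Sox5 (0.0612), Sox30 (0.062), Tekt2 (0.0632), Tekt4 (0.0656), Armc4 (0.0882) and Foxj1 (0.0907) missed it, and so did the cilium list (0.268), which also missed it without knockout replicate 1 (0.419) or 2 (0.814).

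Transcripts of the piRNA pathway and germ granule, which make and use the small RNAs of the male germ line, were not shifted as a group. Of 32 tested members, 1 fell, 0 rose and 31 were not called, with a median of 0.15 (limma camera adjusted p = 0.348); adjusted over the list alone, 1 fell. The member that fell was Kif17, also on the list of spermiogenesis regulators. The log2 change of Piwil1, the PIWI protein that carries pachytene piRNAs, was 0.13 (95% confidence interval -0.16 to 0.42). The value was -0.03 for Mael (-0.33 to 0.27), 0.04 for Ddx4, the germ granule helicase (-0.22 to 0.30), and -0.04 for Rnf17 (-0.27 to 0.19), none past the threshold. For Piwil2 the change was 0.34 (0.07 to 0.61), from 5.63 ± 0.12 to 5.97 ± 0.12 log2 RPKM (limma adjusted p = 0.124). For Tdrd1 it was 0.39 (0.12 to 0.67), from 5.46 ± 0.15 to 5.85 ± 0.10 (limma adjusted p = 0.09, and 0.0247 after quantile normalization). Both intervals lay above 0, although neither gene was past the threshold in the full analysis. piRNAs themselves were not analysed here.

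Of 5 tested genes of the family of deaminase domain proteins, Adad2 was the 1 that fell and 0 rose (limma camera adjusted p = 0.296), with a median of -0.14; adjusted over the list alone, 2 fell and 1 rose. Adad1, the germ cell relative of Adad2, was at 5.43 ± 0.09 and 5.09 ± 0.11 log2 RPKM (adjusted p = 0.111; 0.0403 after quantile normalization). Adar, an RNA-editing enzyme, was at 1.48 ± 0.17 and 1.88 ± 0.07 (adjusted p = 0.134).

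Stages before the spermatid showed few called genes. Of 30 early meiotic prophase genes, 1 fell and 1 rose, with a median of 0.22 (limma camera adjusted p = 0.296), and the same numbers were found when adjusted over the list alone. Rec8, a meiotic cohesin, was 2.45-fold lower and Brca2, a recombination protein, 1.55-fold higher. Sycp3, of the synaptonemal complex, was at 6.83 ± 0.16 and 7.12 ± 0.01 log2 RPKM (adjusted p = 0.17). Of 28 pachytene spermatocyte genes, 1 fell and 1 rose, with a median of 0.09 (camera adjusted p = 0.845), again with 1 and 1 adjusted over the list alone. Tex101, a germ cell surface protein, rose from 7.75 ± 0.13 to 8.89 ± 0.04 log2 RPKM, which is 216 to 474 RPKM (adjusted p = 0.000977), and Pgk2, a germ cell phosphoglycerate kinase, was 1.53-fold lower. Of 18 spermatogonial genes, 0 were called, also when adjusted over the list alone, while 18 had a change above 0, with a median of 0.25 (camera adjusted p = 0.0154; adjusted p = 0.58 with an estimated correlation). The changes were 0.40 for Egr4 (limma adjusted p = 0.0779) and 0.38 for Crabp1 (limma adjusted p = 0.0812), beside a median of 0.14 over all genes tested. Without wild type replicate 2 Rec8 (adjusted p = 0.081), Brca2 (0.0989), Pgk2 (0.144) and the spermatogonial list (0.0737) missed the threshold, as did Pgk2 (0.171) and the spermatogonial list (0.517) without knockout replicate 2.

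Markers of Sertoli cells, the somatic cells that support germ cells, were higher as a group. Of 25 tested members, 2 rose, 0 fell and 24 had a change above 0, with a median of 0.30 (limma camera adjusted p = 0.000481; adjusted p = 0.58 with an estimated correlation). Adjusted over the list alone, 6 rose. The median over all genes tested was 0.14, and the acrosome and elongating spermatid lists in the same libraries had medians of -1.80 and -2.11. Mro was 1.39-fold higher and Espn, an actin-bundling protein, 1.32-fold higher. Without knockout replicate 2 the list was not past the threshold (adjusted p = 0.405) and nor was Espn (0.119). Without knockout replicate 1 Mro (0.0551) and Espn (0.0558) missed it, and without wild type replicate 2 Mro (0.168) and Espn (0.185) did.

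The other somatic lists were not shifted. Of 22 Leydig cell genes, 1 fell and 0 rose, with a median of 0.17 and a camera direction below that of other genes (limma adjusted p = 0.998). The member that fell was Nr4a1, a nuclear receptor, 1.58-fold, while the log2 change of Nr5a1, a regulator of steroid synthesis, was 0.33 (adjusted p = 0.104). Of 16 peritubular and endothelial genes, 1 fell and 0 rose, with a median of 0.19 (adjusted p = 0.393). This was Actg2, a smooth muscle actin, at 3.69 ± 0.12 and 1.35 ± 0.57 log2 RPKM (5.03-fold lower, adjusted p = 0.00854), while the log2 change of Acta2, the other actin named, was 0.31 (adjusted p = 0.118). Of 15 macrophage and immune genes, 1 fell and 0 rose, with a median of 0.13 (adjusted p = 0.845). Aif1 was at 4.79 ± 0.18 and 2.30 ± 0.50 (5.63-fold lower, adjusted p = 0.00509), while the log2 change of Fcer1g was 0.26 (adjusted p = 0.215). In each of these lists the same counts held when adjusted over the list alone. A change above 0 was found in 14 of the 16 peritubular and endothelial genes and 14 of the 15 immune genes. The median over all genes tested was itself above 0, at 0.14, so these counts alone do not show a shift. Whole-testis RNA does not show which cells the lower Actg2 and Aif1 transcripts came from. Actg2 (adjusted p = 0.0584) and Nr4a1 (0.175) missed the threshold without wild type replicate 2.

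Haemoglobin transcripts, a sign of blood in the tissue, were highest in wild type replicate 1. Hbb-b1 stood at 4.93, 3.87, 3.41 and 3.79 log2 RPKM in wild type replicates 1 and 2 and knockout replicates 1 and 2, and Hba-a2 at 4.72, 3.58, 3.17 and 3.45. Each has a near-identical copy that may share reads. Of 5 tested red blood cell genes 0 were called, also when adjusted over the list alone, with a median of -0.80 (limma camera adjusted p = 0.0412; adjusted p = 0.58 with an estimated correlation). The list was not past the threshold without wild type replicate 1 (adjusted p = 0.194), without knockout replicate 1 (0.239) or after quantile normalization (0.0534).

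The interferon and stress response lists were not past the threshold as groups. Of 31 interferon response genes, 9 reached the filter, and the rest were not tested. Of the 9 tested, 0 were called, also when adjusted over the list alone. All 9 had a change above 0, with a median of 0.25 (limma camera adjusted p = 0.295) beside 0.14 over all genes tested. The log2 change of Oasl2, an interferon-induced gene, was 0.44 (adjusted p = 0.192). Of 21 p53 and stress response genes, 1 rose and 1 fell, with a median of 0.21 (camera adjusted p = 0.378), and 2 rose and 1 fell when adjusted over the list alone. Jun, a transcription factor of immediate responses, was 1.51-fold higher and Asns, asparagine synthetase, 1.43-fold lower. Without wild type replicate 2 Jun (adjusted p = 0.188) and Asns (0.106) missed the threshold, and without knockout replicate 2 Jun did (0.108).

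**Figure D3:**
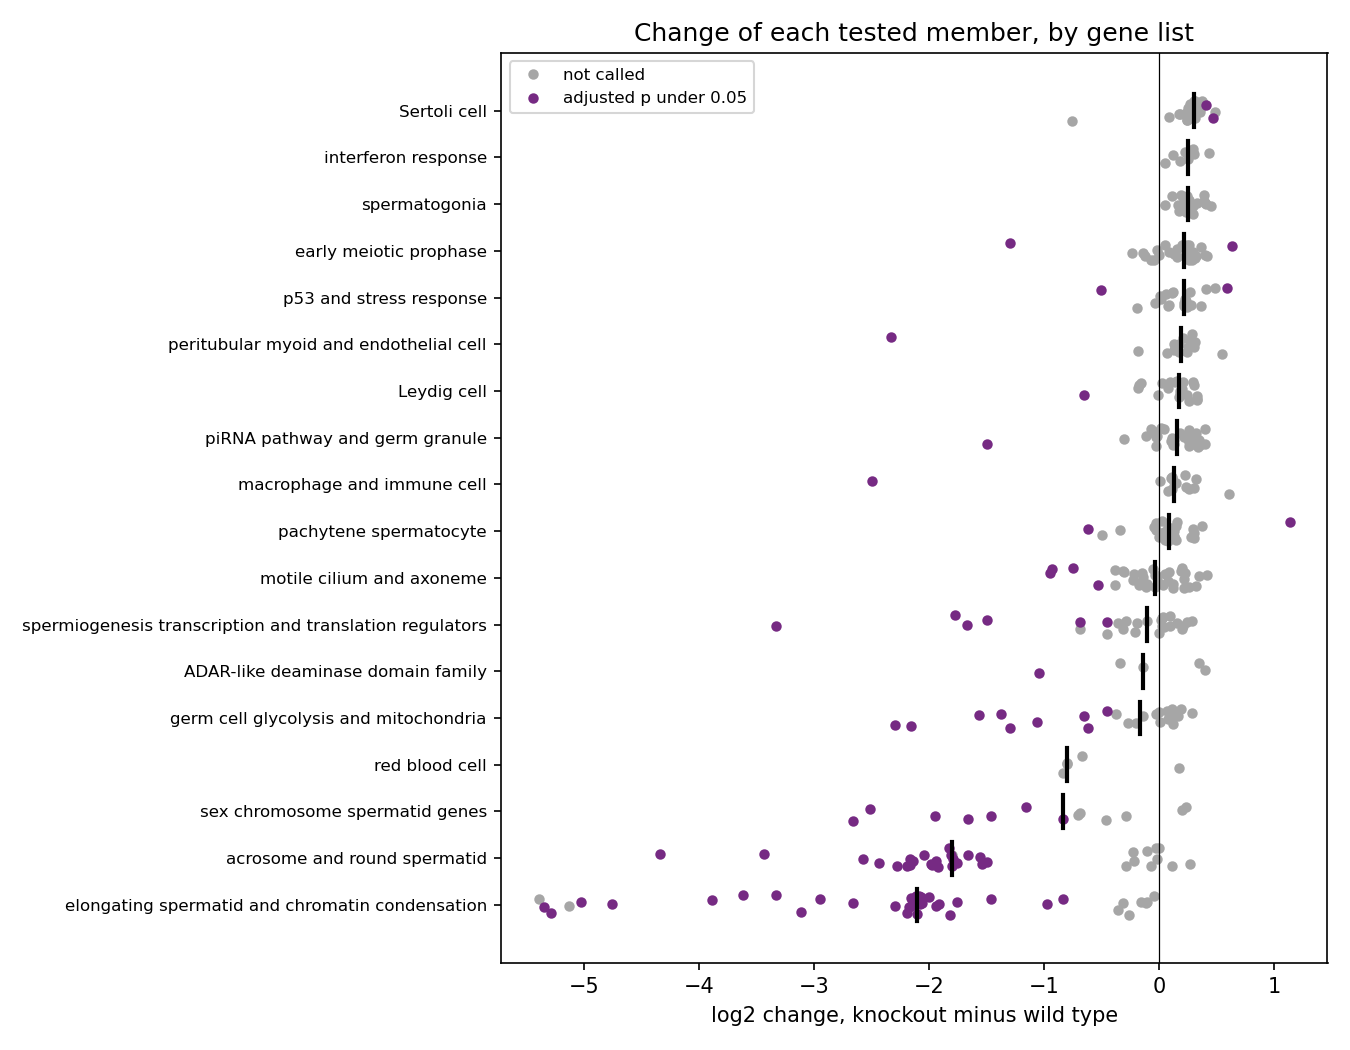
Log2 change (knockout minus wild type) of each tested member of the 18 gene lists, with purple points for adjusted p under 0.05 over all genes, grey points for the rest and black bars for list medians. The elongating spermatid and acrosome lists have medians of -2.11 and -1.80, while the piRNA pathway list has 0.15 with Kif17 apart from its other members.

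Genes on chromosome X, which is silenced in pachytene spermatocytes and partly active again in spermatids, were not shifted as a set. Of 527 tested, 60 fell and 4 rose (75 and 14 adjusted over the list alone). The median was 0.20, the mean -0.07 and the camera direction downward (limma adjusted p = 0.768), so the summaries differ in sign. Without wild type replicate 2 the downward shift passed the threshold (adjusted p = 0.0172). Of 12 genes on chromosome Y, 0 were called, also when adjusted over the list alone, with a median of 0.20 (adjusted p = 0.768).

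The increases were smaller and the genes named belonged to no single list. Genes with clone or predicted names were left out, among them the 2 largest called increases, which were above that of Stambp. Ptchd3, a patched-domain gene, was at 4.27 ± 0.06 and 5.60 ± 0.25 log2 RPKM, 2.51-fold higher. Pard6g, a cell polarity gene, was 2.45-fold higher, Zfa, a zinc finger gene related to Zfx, 2.28-fold, and Prelid1, a mitochondrial lipid transfer protein, 2.10-fold (limma adjusted p = 0.000493). The histone genes Hist1h4h and Hist2h2ab were 2.32-fold and 2.18-fold higher. Reads of Zfa and of the histone genes may be shared with near-identical relatives. Pard6g (adjusted p = 0.0831), Hist1h4h (0.0606) and Hist2h2ab (0.0705) missed the threshold without wild type replicate 2.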

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

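The rule by size alone, without a test, was chosen after seeing the data; the other alternatives were planned. With 4 libraries the spread is poorly known, and a change of 0.5 on the log2 scale was seldom recovered in simulated data. Genes higher in the knockout, 163 in the full analysis, numbered 97 without a filter (48 shared), 542 at an adjusted p under 0.1, 19 with a change of at least 1, and 0 to 494 when a library was left out. Genes lower, 959 in the full analysis, numbered 637 with the filter at a mean of 2 (584 shared), because fewer genes were tested, and 0 to 1308 when a library was left out. Counting genes in which every knockout library differed from every wild type library by at least 1 gave 557 lower and 9 higher. Quantile normalization shared 954 of the lower and 152 of the higher calls, and equal medians 950 and 156.

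The replicate numbers are shared between groups, but no label gives a shared litter or day. Deviations from the group means correlated at 0.331 between same-numbered libraries. With the replicate block 1837 genes were higher and 1477 lower, so 55.4% of calls were higher against 14.5% without the block. Of the named genes, 7 gained the threshold with the block (Acta2, Adad1, Adar, Crabp1, Egr4, Nr5a1 and Tdrd1) and 4 lost it: Prm1 (adjusted p = 0.0985), Tnp1 (0.0889), Prm2 (0.117) and Spem1 (0.13).

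The camera test with an estimated correlation could call few shifts with so few libraries. Its adjusted p was 0.58 for the acrosome, elongating spermatid, regulator, glycolysis and sex chromosome lists. It was also 0.58 for the spermatogonial, Sertoli and red blood cell lists, and 0.807 for the motile cilium list. Leaving out single libraries gave an adjusted p of 0.00613 to 0.517 for spermatogonia, 4.79e-06 to 0.405 for Sertoli cells, 0.000765 to 0.814 for the motile cilium, 0.000229 to 0.239 for red blood cells and 0.0172 to 0.514 for chromosome X. The motile cilium list gave 0.0615 without a filter and 0.0983 with the replicate block. The red blood cell list gave 0.102 without a filter, 0.0534 after quantile normalization and 0.0569 without trend and robust estimation. The cause of these changes was not tested. The acrosome, elongating spermatid, regulator, glycolysis and sex chromosome lists stayed past the threshold in every alternative except the estimated correlation. The change of Adad2 ranged from -1.26 to -0.84 when a library was left out. Of 69 named genes tested besides Adad2, 51 passed the threshold; 51 lost it without wild type replicate 1 and 23 without wild type replicate 2. Without a filter 7 lost it and without trend and robust estimation 5, among them Crem, Espn, Foxj1, Mro and Pgk2 in both. Adad1 and Tdrd1 gained it after quantile normalization.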

Other observations

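The tests of scaling, carried-over RNA, few reads, gene types, ribosomal and histone genes and chromosome X, and the simulation of shared wild type libraries, were chosen only after the results were seen, as were the genes named here; those of the first wave, of the Sertoli shift and of the region around Adad2 were chosen before, but the result of the first wave was judged undecided only after it was seen. The values of some genes stand out beyond the comparisons. Actg2 and Stambp lie side by side on chromosome 6, Actg2 from 83462899 to 83486259 and Stambp from 83493200 to 83522498, and moved in opposite directions, by -2.33 and 1.45 on the log2 scale. Tnp2, the other transition protein, was at 7.72 and 7.58 in wild type and 3.27 and 1.23 in the knockout, a change of -5.39 (SE 0.84) that missed the threshold (limma adjusted p = 0.0761). Gsta2, a glutathione transferase, was at -1.98 in wild type replicate 1 and at 1.89, 2.86 and 3.13 in wild type replicate 2 and the knockout libraries, and Zfp125 at -2.45 against 1.78, 1.70 and 1.59. Cst9, a Sertoli cell cystatin, was at 4.73 in knockout replicate 1 and at 6.55, 6.48 and 6.78 in wild type replicates 1 and 2 and knockout replicate 2. Of 33 entries that name no gene and reach the filter, 0 were higher by at least 1 in every knockout library and 1 was lower, on chromosome 3 from 105673776 to 105726954, at 2.05 ± 0.17 log2 RPKM in wild type and -2.05 ± 1.56 in the knockout (SD, n = 2 each).

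Of 81 ribosomal protein genes, 71 had a change above 0 and 3 rose, with a median of 0.17 against 0.14 over all genes tested, and 0.16 after quantile normalization or with equal medians (limma camera p = 0.00683; p = 0.485 with an estimated correlation). Of 17 tested histone genes, taken by symbols that start with Hist1h to Hist4h, 3 rose and 3 fell, with a median log2 change of -0.033. The symbols alone do not show which genes are replication-dependent, and the median is the value of a single gene, Hist1h2ba. The set therefore does not decide whether replication-dependent histone transcripts were retained. Hist2h2ac rose by 0.98 and Hist1h4a fell by 1.65. Genes without a protein-coding type made up 18% of the 150 higher genes with a Gencode type, 12.4% of the 895 lower genes and 7.6% of 11745 genes not called (two-sided Fisher's exact p = 3.49e-05 and 1.83e-06). On chromosome X 11.4% of tested genes fell, against 6.98% elsewhere (odds ratio 1.71, 95% confidence interval 1.28 to 2.27, two-sided Fisher's exact p = 0.000367); genes are not independent in these tests.

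The fall of the 73 spermatid genes (acrosome and elongating lists) is the first pattern. A difference in depth or scaling would move all genes alike. After quantile normalization the median change was -1.98, while the central 95% of 10000 random lists matched on expression had medians from 0.06 to 0.17. The gap to other genes was known before this test was chosen, so the test only restates it. The gap itself argues against a scaling of whole libraries. An earlier point of the first wave stays open: across the 73 genes, those lower in wild type replicate 2 than in replicate 1 tended to be further down in the knockout (Spearman rho = 0.248, permutation p = 0.0347; Pearson r = 0.202, and 0.17 without the genes farthest from the median). This met the rule set beforehand but decides nothing, because it compares single wild type libraries that both measures use, and the simulated central 95% with no relation (-0.23 to 0.229) took genes as independent and the wild type testes as equally variable. A block at the start of spermatid formation could give the same relation, and with a single age the data do not separate a delay from a block or from a lower level per cell.

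In the second pattern, 72 of the 73 spermatid genes were lower in knockout replicate 2 than in knockout replicate 1, by a median of 0.49 on the log2 scale. A scaling of whole libraries is argued against by the gap to all tested genes, whose median difference was -0.025. After quantile normalization the median difference was -0.435, against -0.035 to 0.053 in the central 95% of random matched lists. This restates the gap, which was known before the test was chosen. Wild type RNA carried into knockout replicate 1 is argued against as the whole cause. There Prm1, Prm2 and Tnp1 stood at 3.87%, 4.22% and 4.6% of their wild type level, and each caps the share carried over. Even the largest of these, 4.6%, would give a median difference of -0.229, against -0.491 observed. In wild type, 53 of the 73 genes were lower in replicate 2 than in replicate 1, with a median difference of -0.133 on the log2 scale. After quantile normalization it was -0.21, also below random lists (-0.015 to 0.064). A difference in stage between the testes may account for this and was not tested.

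The third pattern is the 163 genes higher in the knockout. Of the 150 with an exon length, 1.3% had fewer than 10 estimated reads in a wild type library, which decides nothing about few reads, because the filter left 0.12% of all tested genes there. Loss of spermatid transcripts could raise the share of all others: with the knockout libraries lowered by 0.30, the median change of the Sertoli list, 37 of the 163 genes were still called higher and 2119 genes lower. The 37 genes were 22.7% of the 163, between the limits set beforehand for either answer. Such a rise in share therefore stays open for all 163 genes. The 37 are the calls that cleared a shift taken from the same libraries, so they are not separate evidence against it. Passenger variants of a parental strain near the edited gene could also change expression, but 8.12% of 160 tested genes within 10 Mb of Adad2 were called against 8.37% elsewhere (odds ratio 0.968, 95% confidence interval 0.502 to 1.72), which neither shows nor excludes an excess; among them Osgin1 fell by 1.53 (limma adjusted p = 0.00131).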
